A study of Mus musculus with 2 samples.

How the data were processed

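Peritoneal macrophages are phagocytes of the abdominal cavity. The labels describe cells of C57BL/6J mice, pooled from males and females, at a stage recorded as embryonic day 15.5. There was 1 library from cells given the solvent DMSO and 1 from cells given GW3965, a synthetic agonist of the liver X receptors (LXRs), the nuclear receptors that sense oxidised cholesterol. The dose and the length of treatment are not given in the sources used here. Per the labels' protocols, total RNA was isolated with a Qiagen kit and libraries were made with the Illumina TruSeq RNA kit. No label states that the kit kept strand information.

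The authors deposited 1 table of FPKM values, fragments per kilobase of gene scaled to the sequencing depth, with 50608 rows and 1 column per library. The submitters' processing notes name STAR 2.3.0 and HTSeq 0.5.4p3 and the mouse build GRCm38 (mm10), with no role or order. The annotation, the strand setting, the treatment of reads with several matches and any filter are not given in the sources used here. The rows carry gene symbols or NONCODE identifiers, the latter in 25979 rows, and a NONCODE row has no position or gene name in the reference used here. The DMSO column is named after the DMSO sample's description. The other column shares its opening letters with the GW3965 sample's description and with no other sample, but it ends in different letters that no label explains. It was taken as the GW3965 library on that match alone, and every statement on GW3965 below rests on it.

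The depth was recovered from the steps of the FPKM values. Low values of the columns differed by whole-number ratios once 1 factor, 1.35, was allowed between the libraries. Of 29845 rows below 0.3 FPKM in the DMSO library, 97.0% gave a ratio of whole reads with a denominator up to 60, within the rounding of the last printed decimal, against 19.6% when the factor was moved by 1%. Exon lengths of GENCODE release M21, which is on GRCm38, then gave the depth itself. With a length reduced by 99 bases, 191 of 7457 rows pointed to the same depth, against 62 at the next best reduction, as a read length of 100 bases would give. The depths were 101866071 reads for DMSO and 75287119 for GW3965. In most rows the M21 length differs from the length the authors divided by, so reads per gene are estimates. Each fold with a counting interval uses these estimated reads and an exact conditional (Clopper-Pearson) 95% interval. These intervals cover counting error only and say nothing about the spread between mice or cultures.

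For each row the log2 of (GW3965 FPKM + 1)/(DMSO FPKM + 1) was computed, a scale that understates the change of low genes. A gene counted as measured at a mean FPKM of at least 1, and as higher or lower at 1.5-fold or more on that scale. With 1 library per group there is no replicate check, no test of the treatment and no p-value across genes. The median log2 ratio of the measured rows was 0.24, so most values are also given relative to that median and are then called centred.

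The 6 main gene lists, 17 further lists and 13 lists of markers of other cell types and of sex, 36 in all with 577 entries, were fixed before the data were examined. So were the rule for named genes and the alternatives. Symbols were also matched through RefSeq synonyms, and 20 entries had no matching row. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, each member drawn from the 200 measured rows nearest in mean FPKM. A median outside the central 95% of them was called apart, as a description of these libraries. Lists with fewer than 3 measured members got no percentile, a limit set after the data were seen, which left 27 lists with one. Named genes are the 10 highest and 10 lowest log2 ratios among measured rows, all measured members of the LXR target and Abca1 locus lists, and up to 4 members of each other list with the largest absolute log2 ratio. Some genes that meet this rule are not reported here. Other genes are named as a paralogue, in a test, or after their values were seen, as the text says.

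The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, scaling to the same sum of FPKM, centring on the median, scaling to the same upper quartile, a 2-fold limit, leaving out symbols that begin with Gm or end in Rik, an exact conditional test on the recovered reads, and random lists not matched on expression. Leaving out NONCODE, Gm, Rik and pseudogene rows, centring together with a 2-fold limit, and the Abca1 locus list without Abca1 or without Abca1 and AI427809 were added after the data were seen. The calculations were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data the depth step recovered both simulated depths and length reductions. There every gene had the very length used for the recovery, unlike most rows of the real libraries. The exact test, run on 8920 simulated genes, found 99.0% of 200 genes changed 2-fold and called 0.092% of the unchanged ones. Those simulated reads held counting error only, with no spread between cultures and no general shift between the libraries. The 2 rates therefore do not carry over to the real libraries, where 7573 of 8920 rows passed the test. Of 200 simulated lists of 20 unchanged genes, 6.0% were called apart, and 100% were called after a shift of 0.3 on the log2 scale. Those lists were rows drawn at random with shuffled log2 ratios, so they held no genes that vary together. Their rates do not carry over to the real lists either.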

Results

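RNA of peritoneal macrophages was sequenced in 2 libraries, 1 from cells given DMSO and 1 from cells given the LXR agonist GW3965. The recovered depth was 101866071 reads for DMSO and 75287119 for GW3965. Values are FPKM as deposited, and with 1 library per group no difference below has a replicate check. The column read as GW3965 was matched to its sample by the opening letters of its name only, so its treatment is not beyond doubt. The study's title concerns a long noncoding RNA in the export of cholesterol from macrophages, and the comparison asks which genes differ in level when LXR is activated.

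Abca1 and genes of fatty acid synthesis were among the rows with the highest log2 ratios in the GW3965 library. Abca1, the transporter that loads cholesterol onto apolipoprotein A-I, had the largest log2 ratio of the 11889 measured rows on the scale with 1 FPKM added, with 19.9 FPKM in DMSO and 261 FPKM in GW3965, a ratio of 13.1 (95% counting interval 12.9 to 13.3). Scd1, a desaturase that makes monounsaturated fatty acids, had 15.4 and 132 FPKM, a ratio of 8.62 (8.41 to 8.83). Scd2, Fasn and Ighm were also among the 10 highest on that scale, with ratios of 5.38 (5.31 to 5.45), 4.82 (4.71 to 4.92) and 6.95 (6.60 to 7.33). Ighm, the constant region of the IgM heavy chain, stood at 9.26 FPKM in DMSO and 64.4 FPKM in GW3965. The other 5 of the 10 were Rpl9-ps6, Gm5428, Gm13826 and the NONCODE rows NONMMUG029257 and NONMMUG029258, whose ratios with nothing added were 14.01 and 12.12. Rpl9-ps6, a ribosomal protein copy, had 5.30 and 42.1 FPKM, a rise of 440% of the mean level of its parent Rpl9 (8.37 FPKM). Whether its reads or those of Rpl9 are shared with other copies is not given in the sources used here. The 10 lowest ratios were smaller in size. Among them, Itgb3, the beta 3 integrin, had 14.6 FPKM in DMSO and 7.85 in GW3965, a ratio of 0.537 (0.516 to 0.558). Hist1h4j, a histone gene with near-identical copies, had a ratio of 0.501 (0.381 to 0.649) and Tmsb15l one of 0.471 (0.342 to 0.637). Yam1, annotated in neither reference used here, had 3197 and 1936 FPKM, and the remaining 6 were NONCODE rows.

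At 1.5-fold, 411 rows were higher and 9 were lower in the GW3965 library. After centring on the median of the measured rows, 164 were higher and 40 lower, so that the share of higher rows among those called went from 97.9% to 80.4%. At 2-fold the counts were 117 and 0 as deposited, and 80 and 3 after centring. The central 90% of centred log2 ratios ran from -0.27 to 0.28. Among 8494 protein-coding rows that are not pseudogenes, 181 were higher and 3 lower, or 65 and 21 after centring. NONCODE rows gave 149 of the higher and 5 of the lower rows, or 46 and 14 after centring. The shift went with the makeup of the libraries. Rows with a GENCODE length held an estimated 66.9% of reads in DMSO and 80.3% in GW3965, and 3 NONCODE rows above 200000 FPKM in each library made up 79.7% and 65.9% of the FPKM sums. Olfactory receptor genes, most of which are silent outside sensory tissue, had a median of 0.026 FPKM in DMSO and 0.069 in GW3965 over 1083 rows.

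**Figure D1:**
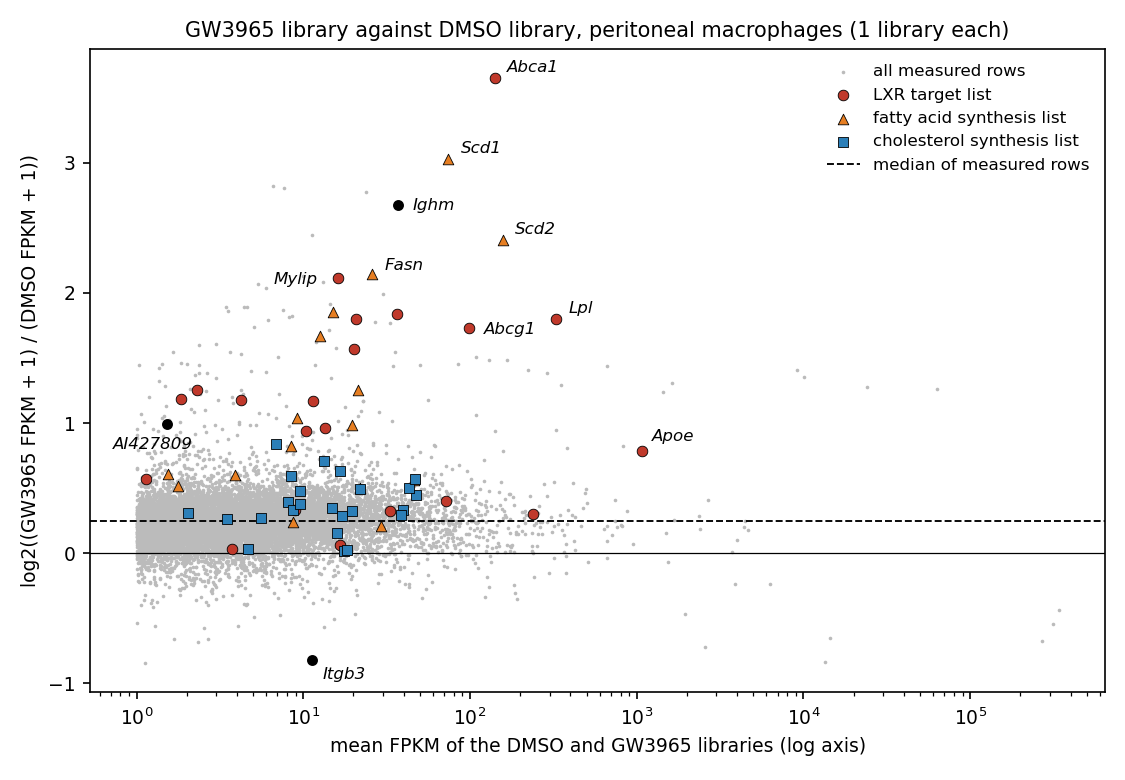
Each point is 1 measured row, with the mean FPKM of both libraries on a log axis and the log2 ratio of GW3965 to DMSO (FPKM + 1) on the vertical axis. Filled symbols mark 3 gene lists and black points 3 further named genes, and the dashed line is the median of 0.24. Abca1 lies highest at 3.65, and the cholesterol synthesis genes lie near the dashed line.

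The list of known LXR targets was higher as a group in the GW3965 library. Of 21 measured members, 14 were higher by 1.5-fold and none was lower, and 13 were still higher after centring. Their median log2 ratio was 1.17, or 0.93 after centring, and it lay above all 10000 random lists. Besides Abca1, the sterol transporter Abcg1 had 45.3 FPKM in DMSO and 153 FPKM in GW3965, a ratio of 3.37 (3.33 to 3.42). Lipoprotein lipase (Lpl) had a ratio of 3.50 (3.48 to 3.52), the phospholipid transfer protein Pltp 3.75 (3.61 to 3.89) and the lipogenic transcription factor Srebf1 3.77 (3.65 to 3.90). Mylip, the ubiquitin ligase that degrades the LDL receptor, had 5.41 and 26.8 FPKM, a ratio of 4.95 (4.69 to 5.22), and Lpcat3, which remodels membrane phospholipids, had a ratio of 3.17 (3.04 to 3.30). Cd38 (3.97), Apoc2 (3.84), Cd5l (2.84), Arl4c (2.44), Tgm2 (2.05) and the engulfment receptor Mertk (2.05) were higher on both scales. Apoe had 788 FPKM in DMSO and 1358 in GW3965, a ratio of 1.72 (1.71 to 1.73) and a centred log2 ratio of 0.54, which is below the 1.5-fold limit. Arg2 had a centred log2 ratio of 0.33, and Smpdl3a, Nr1h3 (LXR alpha itself), Npc1 and Npc2 had 0.16, 0.09, 0.08 and 0.06. Abca7 had a ratio of 1.03, and its sign depended on the scaling, with a centred log2 ratio of -0.21.

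Genes of fatty acid synthesis were also higher as a group. Of 16 measured members 11 were higher by 1.5-fold and none lower, and 8 were higher after centring. Random lists all lay below their median log2 ratio of 0.91, or 0.66 after centring. Scd1, Scd2 and Fasn, the fatty acid synthase, are given above. Fads2, a desaturase of polyunsaturated fatty acids, had 5.99 FPKM in DMSO and 24.3 FPKM in GW3965, a ratio of 4.05 (3.85 to 4.27).

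Genes of cholesterol synthesis and uptake lay much closer to the median of all rows. Of 24 measured members 4 were higher by 1.5-fold, 1 after centring, and none was lower on either scale. At a median log2 ratio of 0.34, or 0.09 after centring, the list lay at the 96.7th percentile of random lists and so within their central 95%. That call changed with the setting, since 6 of the 7 alternatives that could move it placed the list above the random range. Pmvk had 4.67 and 9.15 FPKM, a ratio of 1.96 (1.79 to 2.15). Acat2 had a ratio of 1.70 (1.61 to 1.79) and Lss one of 1.59 (1.54 to 1.64). Both were below the limit after centring, with log2 ratios of 0.46 for Acat2 and 0.35 for Lss.

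The Abca1 locus list holds genes near Abca1 on chromosome 4 and AI427809, the long noncoding RNA known as MeXis. AI427809 lies at 53261356 to 53270232 on the minus strand of GRCm38, 101460 bases from the 5' end of Abca1, which spans 53030787 to 53159895 on the same strand. It is annotated as a long intergenic noncoding gene. It had 0.688 FPKM in DMSO and 2.36 FPKM in GW3965, an estimated 159 and 404 reads and a ratio of 3.43 (2.85 to 4.16). Of 9 measured members of the list 4 were higher by 1.5-fold, and Abca1 and AI427809 were still higher after centring. With a median log2 ratio of 0.47, or 0.23 after centring, the list lay at the 99.96th percentile of random lists. Nipsnap3b had 8.75 and 15.8 FPKM, a ratio of 1.81 (1.69 to 1.94), though reads shared with its paralogue Nipsnap3a, listed at 0 in DMSO, cannot be excluded. Slc44a1, a choline transporter gene, had 11.1 and 19.3 FPKM, a ratio of 1.74 (1.69 to 1.79). Their centred log2 ratios were 0.54 and 0.51. Farther away, the centred values were 0.09 for Rad23b, -0.02 for Tmem38b, -0.09 for Smc2 and -0.42 for Klf4. Without Abca1 and AI427809 the list lay at the 90.9th percentile, within the random range.

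**Figure D2:**
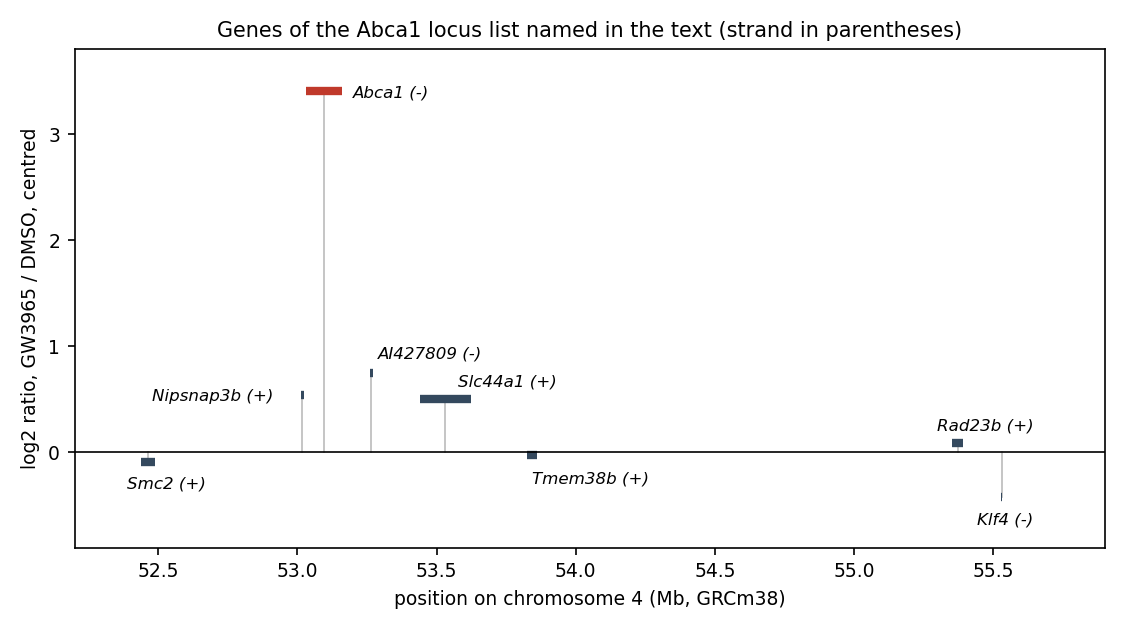
Measured genes of the Abca1 locus list that the text names are drawn to scale along chromosome 4 (Mb, GRCm38), each bar spanning its gene at the height of its centred log2 ratio of GW3965 to DMSO. Abca1 stands at 3.40, AI427809, Nipsnap3b and Slc44a1 beside it between 0.51 and 0.75, and the genes drawn farther off between -0.42 and 0.09.

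Inflammatory genes were described because LXR agonists are known to repress them in stimulated macrophages. No stimulus is named in the labels, and 14 of the 28 listed genes were not measured. Of the 14 measured members 3 were higher by 1.5-fold, 2 after centring, and none was lower on either scale. The median log2 ratio was 0.40, or 0.16 after centring, at the 99.9th percentile, but it lay at the 71.0th percentile with no filter on low values. The cytokine Il1a had 7.39 and 24.0 FPKM, a ratio of 3.25 (3.05 to 3.46), and Tnfaip3, an inhibitor of NF-kappaB signalling, 3.62 and 8.69 FPKM, a ratio of 2.40 (2.29 to 2.52). Tlr4 had a ratio of 1.64 (1.58 to 1.70) and a centred log2 ratio of 0.42, and Saa3 had 47.1 and 70.8 FPKM and a centred log2 ratio of 0.33. Interferon response genes had 17 measured members, none of them higher or lower by 1.5-fold on either scale. Their median log2 ratio was 0.19, or -0.05 after centring, at the 13.7th percentile, and Oas1a had 10.3 and 14.3 FPKM.

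Markers of other cells also differed. The mesothelial and fibroblast markers, 7 of 13 measured, had a median log2 ratio of 0.41, or 0.17 after centring, at the 99.6th percentile, or the 76.7th with no filter on low values. Dcn had 6.91 and 11.6 FPKM and Upk3b 1.38 and 2.51 FPKM. These markers were thus higher in the same library as the LXR, fatty acid, inflammatory and Abca1 locus lists. The dendritic cell markers, 5 of 12 measured, had a median of 0.09, or -0.16 after centring, at the 2.47th percentile. That call was lost under 5 of the 6 alternatives that could move it. Itgax, which macrophages also express, had 116 and 107 FPKM. The B cell markers had 4 measured members at the 77.9th percentile, with Ighm far above Cd79a (1.03 and 1.60 FPKM), Cd79b (0.925 and 1.28 FPKM) and Cd22 (8.20 and 9.11 FPKM). The 19 measured general macrophage genes had a median log2 ratio of 0.23, or -0.01 after centring, at the 30.1st percentile, and Mpeg1 had 635 and 841 FPKM.

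**Figure D3:**
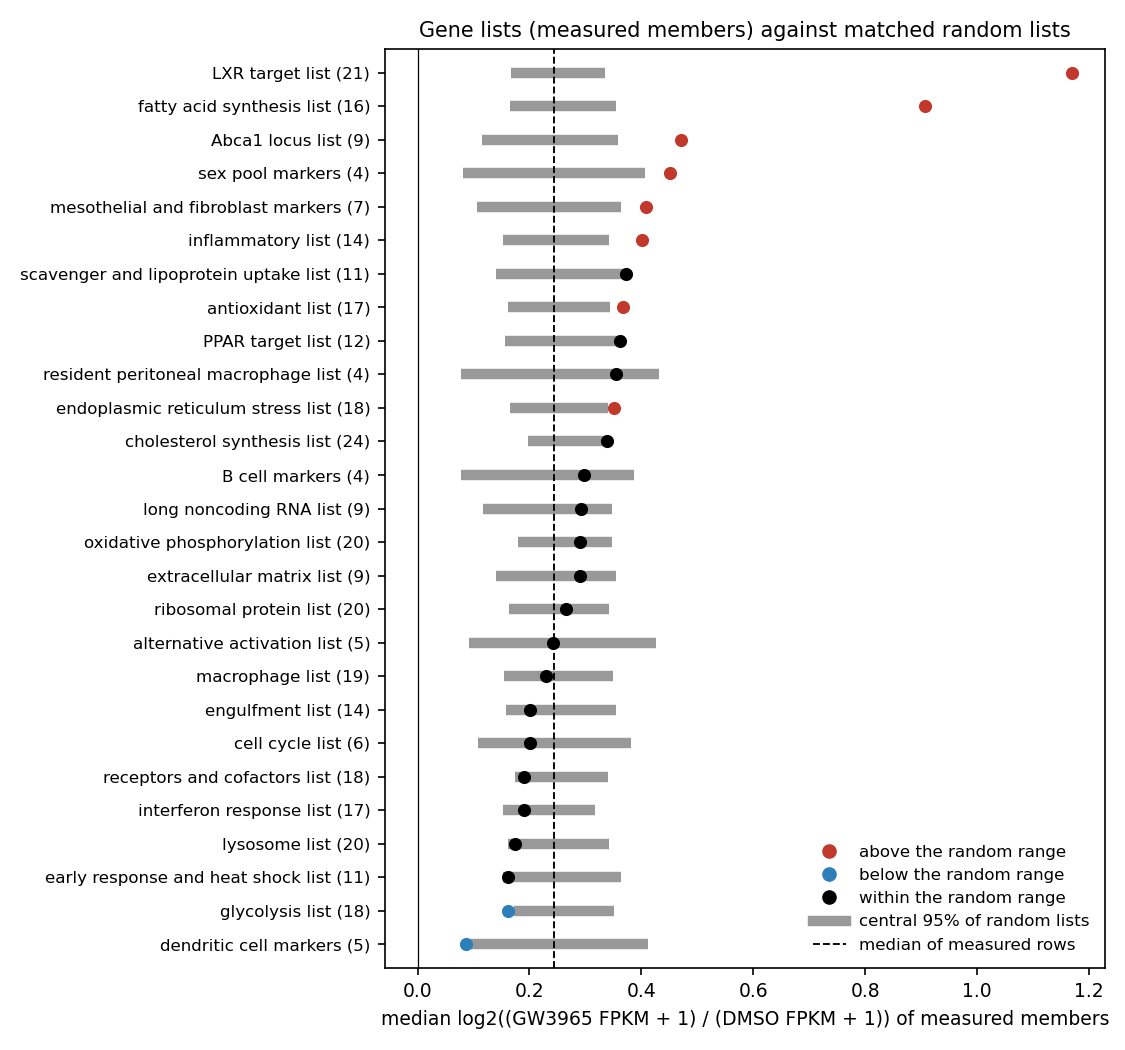
Points are the median log2 ratios of GW3965 to DMSO (FPKM + 1) of the measured members of 27 gene lists, with the number of members in parentheses, and grey bars are the central 95% of 10000 random lists matched on expression. The dashed line is the median of measured rows at 0.24; 8 lists lie above their bar and 2 below, with the LXR list farthest out at 1.17.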

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

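No paired analysis was possible because each group has 1 library. Against 411 rows higher in the GW3965 library, the count was 1024 with a pseudocount of 0.1, 224 at a mean FPKM of at least 5, 2416 with the same sum of FPKM, 164 centred on the median, 165 with the same upper quartile, 117 at 2-fold, and 250 among the 8920 rows with recovered reads. In those rows the exact test took no row away, since 7573 of them passed it and it compares these libraries, not the conditions. Against 9 rows lower, the same settings gave 20, 5, 1, 40, 37, 0 and 3, a pseudocount of 0.5 gave 14 and no filter on low values gave 17. Leaving out NONCODE, Gm, Rik and pseudogene rows, chosen after seeing the data, gave 188 higher and 4 lower, and centring with a 2-fold limit, also chosen then, 80 and 3. The share of higher rows among those called was 97.9% as deposited, 80.4% centred, 81.7% with the same upper quartile and 99.96% with the same sum.

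Centring moves a list and its random lists alike, and a filter can move neither the ratio of a single gene nor a list whose members it leaves as they were, so these are left out of the tallies here. The LXR, fatty acid and interferon lists kept their call under each of the other 7 alternatives. The cholesterol synthesis list, at the 96.7th percentile, went above the random range with a pseudocount of 0.1 (99.09) or 0.5 (98.17), a mean FPKM of at least 5 (99.55), the same sum (98.92), the same upper quartile (99.3) and random lists not matched (99.46). With no filter on low values the inflammatory list went to 71.02 and the Abca1 locus list to 60.8, where both gained unmeasured genes near 0. Leaving out Abca1 kept the locus list apart, and leaving out Abca1 and AI427809 put it at 90.85, both chosen after seeing the data. Apart from those gains and left out genes, the cause was not tested. Of 113 values of the further and marker lists 98 kept their call, 12 lost it and 3 gained it, and 0 changed direction. Of 735 values of single named genes 623 stayed on their side of 1.5-fold, 40 lost it, 72 gained it and 0 changed direction past it. Depth limits genes near 1 FPKM, where 1 read of a 1 kb gene is worth 0.0109 FPKM in DMSO and 0.0147 in GW3965.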

Other observations

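Several other gene groups differed between the libraries by small amounts. Endoplasmic reticulum stress genes, 18 measured, had a centred median of 0.11 at the 98.8th percentile of random lists, with Hsp90b1 at 55.2 FPKM in DMSO and 80.7 in GW3965 and Hspa5 at 78.5 and 107 FPKM. Their call was lost under 4 of the 5 alternatives that could move it. Antioxidant genes, 17 measured, had a centred median of 0.12 at the 99.4th percentile, a call lost under 1 of 5, with Gpx1 at 98.1 and 145 FPKM. None of the members of either list was higher by 1.5-fold after centring. Glycolysis genes, 18 measured, lay low among random lists, at the 1.5th percentile with a centred median of -0.08, although as deposited their median log2 ratio was 0.16. This call was lost under 1 of 5 such alternatives. Vegfa, counted in that list, went the other way, with 4.18 and 9.64 FPKM. Lipid uptake genes were close to the upper limit in the main setting. Scavenger and lipoprotein uptake genes lay at the 97.2nd percentile, and from 71.34 to 97.36 under their 6 alternatives. PPAR targets lay at the 96.5th. They gained a call of higher under 1 of 6 alternatives, which ran from 90.57 to 98.62. Among members of these lists, the scavenger receptor Msr1 had 10.3 and 21.9 FPKM. The fatty acid transporter Cd36 had 277 and 484 FPKM, and the lipid droplet protein Plin2 224 and 432 FPKM. Early response and heat shock genes lay at the 3.55th percentile and gained a call of lower under 2 of 6 alternatives, at down to the 1.72nd. In that list the chaperones Hsph1 (5.54 and 10.2 FPKM) and Hspa1a (0.902 and 2.08 FPKM) lay above the rest.

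Of the remaining lists, 10 stood within the range of random lists. Their percentiles were 5.84 for receptors and cofactors, 12.0 for engulfment, 41.9 for alternative activation, 90.4 for resident peritoneal macrophages, 4.4 for lysosome, 74.2 for oxidative phosphorylation, 58.7 for ribosomal proteins, 26.3 for cell cycle, 83.9 for long noncoding RNAs and 77.2 for extracellular matrix genes. Some of these lists rested on few genes, with 5 of 16 measured for alternative activation and 6 of 20 for cell cycle. The resident peritoneal macrophage list had 4 of 16 measured and lay between the 3.15th and 85.03rd percentiles under its 6 alternatives. Among its 12 genes that were not measured was Gata6, at 0.607 and 0.618 FPKM, picked after its value was seen. In the engulfment list C1qb had 23.0 and 39.9 FPKM against 14.6 and 7.85 for Itgb3. Too few marker genes were measured for a percentile of 9 lists. The T and NK cell, eosinophil, platelet and adipocyte lists had 1 measured member each, the neutrophil, inflammatory monocyte and endothelial lists 2 each, and the mast cell and erythroid lists 0. The 4 measured Y-linked genes of the sex pool list lay above that range, at the 99.04th percentile, with Ddx3y at 6.59 and 10.2 FPKM, while Xist, picked after its value was seen, had 0.011 and 0.030 FPKM against a label of pooled sexes. The X-linked counterparts Ddx3x and Eif2s3x, picked after their values were seen, had ratios of 1.35 and 1.47. Ddx3y and Eif2s3y had ratios of 1.55 and 1.43. Gapdh had only 5.92 and 6.02 FPKM against 778 and 975 FPKM for Actb, both picked after their values were seen. The rows Gm10800, Gm10801 and Gm21738, picked in the same way, had ratios of 2.42, 2.65 and 2.56, near the 2.64 of the olfactory receptor rows. Their levels in DMSO were 14115, 5025 and 5668 FPKM, far above those rows.

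Of the tests that follow, 7 were chosen after the result was seen. The test on the same share of the parent gene's reads was among these 7. Those on copies split by a parent at 20 FPKM, on antibody secreting cells and on neighbours of other higher genes were set before. Pseudogene rows were higher in the GW3965 library. Of 62 measured, 34 were higher by 1.5-fold and 0 lower, or 30 and 1 after centring. The different scaling of the libraries was argued against as the whole cause, because the centred median was 0.56 with a bootstrap interval from 0.14 to 0.77. Whether more genomic background was the cause could not be decided. The median ratio of the 62 rows was 2.20, with an interval from 1.59 to 3.19 that holds the 2.64 of the olfactory receptor rows. Of 60 pseudogene rows with estimated reads, 21 had lower counting bounds above 2.64, which background with that ratio in each row would not give. The olfactory receptor rows had a median of 0.069 FPKM in GW3965. Each measured pseudogene row had a mean of at least 1 FPKM, but the filter on measured rows fixed that. Background as a part of the cause, or above that level, stays open. The same share of the parent gene's reads counted on its copy in both libraries was argued against as the whole cause. On a log2 scale with 0.1 added, 22 of 23 named copies with a mean of at least 0.1 FPKM had a higher ratio than their parent. The median difference was 1.28, with an interval from 0.68 to 1.84. Only 10 of these copies were measured, 9 of them above their parent, with a median difference of 1.75 over the 10. A larger share of the parent's reads in the GW3965 library stays open. On the same scale, 11 named copies with a parent at 20 FPKM or more were set against 12 other copies. The first group's median minus that of the second was -0.17, with an interval from -1.24 to 1.10 and a one-sided permutation p of 0.62. The copies were too few to decide. The split also rests on the parent's deposited FPKM, which reads shared with copies could lower. Rpl9 counted as a parent below 20 FPKM, at 8.37, while the ribosomal protein gene Rplp1 had 753 FPKM in DMSO. The split may thus not separate high from low parents, and no biological explanation was tested.

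Ighm was higher in the GW3965 library by 6.95 times, with a lower counting bound of 6.60. More B cells in that library were argued against as the whole cause, because the highest upper bound among 8 other B cell markers was 2.87 and their pooled ratio was 1.17 (1.13 to 1.22). That pooled ratio rested mostly on Cd22, and the other 7 markers pooled to 1.55 (1.40 to 1.72), with lower bounds above 1 for 6 of them, so that a smaller rise in B cells stays open. More antibody secreting cells were argued against too, because the highest upper bound of Igj and Mzb1 was 3.79, although Igj rested on an estimated 17 and 24 reads and Mzb1 on 43 and 32. The most abundant of the B cell markers besides Ighm was Cd22, at 8.20 and 9.11 FPKM. No biological explanation was tested, and reads from the NONCODE or unlisted genes of that locus were not examined.

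The genes beside Abca1 were higher in the GW3965 library together with it. The median log2 ratio of the 3 measured neighbours within 500 kb, Nipsnap3b, AI427809 and Slc44a1, lay at the 99.84th percentile of windows around 7516 other coding genes, or the 99.7th of 708 windows with as many neighbours. The 363 neighbours of 58 other coding genes at least 2-fold higher had a median at the 38.1st percentile of random sets. Listed lipid genes and the 58 genes themselves were left out as neighbours. Random sets could keep such higher genes, apart from listed lipid genes, so the comparison leans towards a low percentile. Higher neighbours around any strongly higher gene were thus argued against only for neighbours other than those left out. Reads running past the 3' end of Abca1 were argued against for AI427809 and Slc44a1, which lie beyond its 5' end and had lower counting bounds of at least 1.69, but not for Nipsnap3b, whose rise was 2.93% of that of Abca1 in FPKM and cannot be told apart from such reads without strand information. The pattern rests on 3 genes and 1 library per group, and an effect of the agonist on them was not tested.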
